A study of Mus musculus with 4 samples.

How the data were processed

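Left hemi-brains without the olfactory bulb were taken at postnatal day 5 from Control and NAXD knockout (KO) mice that had been given vehicle or nicotinamide riboside (NR). Per the labels' protocols, nuclei were released with a Dounce homogeniser, purified on an iodixanol gradient, fixed in formaldehyde and hybridised with the GEM-X Flex mouse probes, which read each transcript through probe pairs and not through 3' capture. The protocols state that 300000 fixed nuclei per mouse entered hybridization, that 16 mice were combined into 4 pools of 4 mice and that each pool was run as 1 droplet reaction and 1 library. The submitters' processing notes name Cell Ranger 9.0.1, Seurat and the GRCm39 genome, and the run configuration files name a GRCm39 reference and version 1.1.1 of the Chromium mouse transcriptome probe set. The filters on nuclei, the doublet treatment and the annotation method were not given in the sources used here.

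The authors deposited a table with 1 line per nucleus, a sample table with 1 line per mouse, and the run metrics of each mouse. UMI counts per nucleus were deposited as raw counts, per the file headers and their whole-number values. The mitochondrial percent of each nucleus was deposited by the authors and did not exceed 0.15, so it had been filtered. The 10 module score columns were deposited by the authors with the gene set named in each column, while the way in which the scores were computed and the reason for choosing these sets were not given in the sources used here. The sets were an ATF4 regulon, the Biocarta death pathway, the Hallmark sets for androgen response, apoptosis, G2/M checkpoint, hypoxia and mitotic spindle, and the Reactome sets for macroautophagy, regulated necrosis and serine biosynthesis. A score can fall below 0, so scores are given as differences and never as folds. Cell types were the authors' own annotation, 16 types that matched 16 clusters (resolution 0.08) one to one. Gene-level counts, the level of Naxd itself included, were not analysed here, so the knockout was taken from the sample table alone.

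The pool labels name no treatment group, so the genotype, treatment and litter of each mouse came from the deposited sample table. The groups in the sample table matched those in the run configuration for 16 of 16 mice and those in the cell table for 16 of 16 mice. Wild-type and heterozygous mice were both called Control by the authors and were kept together. The 4 groups of 4 mice were compared in 6 contrasts: KO against Control with vehicle, KO against Control with NR, NR against vehicle in KO, NR against vehicle in Control, NR KO against vehicle Control, and the difference between the NR effects in KO and in Control. The mouse was the replicate in every test, and nuclei were never treated as replicates. The tests, groups and most alternatives were fixed before the data were examined. The scores by cell type, the equal-weight scores, the isolating person as a block, the litter as a block, the UMI window for scores and the removal of particular cell types or mice were added after the columns or values had been seen.

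Shares of cell types were computed per mouse from the number of nuclei of a type over all nuclei of the mouse, as log2 odds with a pseudocount of 0.5 nuclei, for types with at least 10 nuclei per mouse on average. All 16 mice entered 1 limma fit (limma 3.58.1 in R 4.3.3, 12 residual degrees of freedom before moderation) with Benjamini-Hochberg adjustment over the cell types of a contrast and a threshold of 0.05. A fitted log2 odds difference for a type with no nuclei in a group depends on the pseudocount, so folds for that type use a floor of 3 counts over the group. Beside limma, 2-sided exact permutation tests were run on 4 mice against 4, with 70 arrangements and a smallest possible p of 0.0286. The interaction was permuted by exchanging treatments within each genotype (4900 arrangements). Broad classes of cell types, fixed before the data were examined, were tested with the exact permutation test adjusted over 9 classes, and with limma. Cell types were named in the text if they passed the threshold in any contrast, and in a contrast without a passing type the 3 with the smallest p were named with their values. Every broad class was named.

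Scores by cell type were the median of each score over the nuclei of a type in a mouse, fitted with limma over 150 pairs of 10 scores and 15 types. Only types with at least 10 nuclei in every mouse entered these fits, which left out Purkinje cells. UMIs per nucleus by cell type were the median log2 UMI count, fitted in the same way over 15 types. Equal-weight scores were the mean of the 15 type medians in a mouse. A change in the shares of the 15 types cannot move them, while a change in the make-up of nuclei within a type can. Overall scores per mouse, over all nuclei, and the mitochondrial percent made a family of 66 exact permutation tests, and nuclei, UMIs, genes, filtering and run metrics per mouse made a family of 54. Wilson intervals (95%) are given for shares of single mice and cover counting error only.

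The deposited cell table held 393197 nuclei, 89.4% of the 439785 cells called in the run metrics, with 21533 to 28904 nuclei per mouse (median 23968). Nuclei had at least 501 UMIs and 406 genes, with medians of 10031 UMIs and 4859 genes. The median UMI count per nucleus ranged over mice from 8434 to 12003, and sequencing saturation over pools from 23.2% to 25.5%. Between 99% and 99.1% of reads per mouse mapped to the probes. At these depths the floor of 3 counts over the nuclei of the NR KO group corresponds to a share of 0.00319%.

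Because mice of a pool shared a droplet reaction, the pool pairs mice across groups by the labels, and a fit with the pool as a block was run as an alternative. Mice of the same pool did not deviate together: the mean correlation of their deviations from the group means over cell type shares was -0.0523, ranging from -0.81 to 0.85 over pairs, and over scores it was 0.00557. The deposited tables also name the person who isolated the nuclei of each mouse. Mice handled by the same person deviated together in their shares, with a mean correlation of 0.309. The value of -0.309 for mice handled by different persons mirrors this largely by construction. Deviations were taken from the group means, and each group held 2 mice of each person. With the litter as a block, 3 of the 5 litters held 1 mouse each and added nothing to the contrasts, which left 13 mice of 2 litters and 8 residual degrees of freedom.

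Alternatives for the shares were edgeR 4.0.16 quasi-likelihood tests on the nuclei counts with plain totals and with TMM factors, DESeq2 1.42.0, a centred log-ratio and an arcsine square root in place of the logit, a pseudocount of 5, other minimums of nuclei, fits on only the groups compared, log2 nuclei as a covariate, robust moderation, and the removal of nuclei under the 10th or over the 95th percentile of UMIs. For scores and UMIs they were means in place of medians and nuclei within a UMI window. The window ran from the 40th to the 60th percentile of UMIs of the cell type, with no minimum of nuclei per mouse set within it. Each mouse was left out in turn for every result. The limma fits were tested on simulated data with the spread between the real mice, with 200 simulations per size. Deviations were drawn independently for each mouse and type or score, without the person, the litter or the constraint that shares add up. Purkinje cells and progenitors were never among the changed types for shares. The rates of false calls below do not cover such structure and can be higher in the real data. For NR against vehicle in KO over 16 types, changes of 0.5, 1 and 2 log2 odds were recovered in 16.8%, 63% and 90% of cases, with 0.538% to 1.35% of unchanged types called. For KO against Control with vehicle over 150 score pairs, changes of 2 and 4 SD between mice were recovered in 22.3% and 98.4% of cases. For UMIs per nucleus of 15 types, NR against vehicle in KO, changes of 4 SD were recovered in 99.2% of cases. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.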

Results

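Single-nucleus RNA profiles were collected from the left hemi-brains of 16 mouse pups at postnatal day 5. Pups were Control or knockout (KO) for NAXD, the dehydratase that restores NADH and NADPH from damaged, hydrated forms. From postnatal day 0 they had been injected every day with saline vehicle or with nicotinamide riboside (NR, 750 mg/kg), a form of vitamin B3 and a precursor of NAD+. Each of the 4 groups held 4 mice. Each of 4 pools held 1 mouse of every group, and 2 persons isolated the nuclei, each from 2 mice of every group. The Control mice were 1 wild-type and 3 heterozygous pups with vehicle, and 2 and 2 with NR. The mice came from 5 litters, and the only litter with mice of all 4 groups held 3 vehicle Control, 1 vehicle KO, 2 NR Control and 2 NR KO mice. The other 2 NR KO mice and 1 vehicle KO mouse were each the only mouse of their litter, so a fit with the litter as a block, added after the data were seen, compared 13 mice within 2 litters (8 residual degrees of freedom). The authors annotated 393197 nuclei as 16 cell types. Each mouse contributed 21533 to 28904 nuclei and 265700000 to 445514000 UMIs. The contrasts ask what the knockout changes without treatment, what NR changes in KO and in Control brains, and whether these NR effects differ. The smallest p that an exact permutation test of 4 mice against 4 can give here is 0.0286.

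In vehicle-treated mice, no cell type share passed the test between KO and Control. Purkinje cells, the output neurons of the cerebellar cortex, made up 1.04% ± 0.163 (SD, n = 4) of nuclei in vehicle KO mice and 0.410% ± 0.308 in vehicle Control mice. The log2 odds difference was 2.63 (SE 1.55, exact p = 0.0286, limma adjusted p = 0.682), with higher values in 4 of 4 pools and within-person differences of 4.07 and 1.19. The vehicle Control mouse of pool 4 carried much of this, and without it the difference was 0.97 (limma adjusted p = 0.872). Upper-layer excitatory neurons of the cortex made up 19.9% ± 4.07 against 24.3% ± 4.04 (-0.38, SE 0.26, lower in 3 of 4 pools). Progenitors, the immature cells that still divide or have yet to mature, made up 13.6% ± 2.94 against 9.05% ± 5.93 (1.19, SE 0.93, higher in 3 of 4 pools), and the difference was 0.25 without the same Control mouse. The differences were 1.60 for Purkinje cells and 0.63 for progenitors with the litter as a block. limma called 0 of 16 types, also 0 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0.

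NR treatment of KO mice was accompanied by the loss of Purkinje nuclei, a fall of progenitors and higher shares of 4 neuron types. Purkinje nuclei fell from 1005 of 97382 in vehicle KO mice to 0 of 93990 in NR KO mice. With the floor taken over the group, this allows a share of up to 0.00319% and is at least 323-fold lower. That bound covers counting error only, and the floor in single NR KO mice was 0.0125% to 0.0135%. The fitted log2 odds difference was -8.93 (SE 1.55, limma adjusted p = 0.000871), lower in 4 of 4 pools. The spread behind this SE was shared by all 4 groups, also in the fit with the litter as a block below. It includes the Control mice, 2 of which had 1 Purkinje nucleus each, while shares in single vehicle KO mice ranged from 0.884% to 1.25%. Progenitors fell from 13.6% ± 2.94 to 0.885% ± 0.133 (SD, n = 4), a log2 odds difference of -4.12 (SE 0.93, limma adjusted p = 0.00481), lower in 4 of 4 pools. Upper-layer excitatory neurons rose from 19.9% ± 4.07 to 30.4% ± 5.64 (0.82, SE 0.26, limma adjusted p = 0.0268). Medium spiny neurons, the projection neurons of the striatum, rose from 6.57% ± 0.703 to 10.2% ± 1.49 (0.69, SE 0.22, limma adjusted p = 0.0268). Interneurons from the medial ganglionic eminence rose from 3.83% ± 0.644 to 5.78% ± 0.845 (0.63, SE 0.22, limma adjusted p = 0.0409). Hippocampal neurons rose from 0.834% ± 0.0878 to 1.22% ± 0.184 (0.55, SE 0.20, limma adjusted p = 0.0427). Each of these 4 rises was seen in 4 of 4 pools.

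The exact p was 0.0286 for each of these types except the upper-layer neurons, for which it was 0.0571. Within persons the differences were -8.99 and -8.87 for Purkinje cells, -4.16 and -4.09 for progenitors, and 0.83 and 0.81 for upper-layer neurons. limma called 6 of 16 types, with 7 at an unadjusted p under 0.05. With the litter as a block 0 types passed: the differences were -7.27 for Purkinje cells (limma adjusted p = 0.194), -3.27 for progenitors (limma adjusted p = 0.247), and 0.65, 0.63, 0.46 and 0.48 for the 4 neuron types in the order above. With Purkinje and progenitor nuclei taken out of counts and totals, a check chosen after the data were seen, 0 types passed in this or any other contrast. The 4 neuron types then differed by 0.55, 0.46, 0.40 and 0.33 without passing, so whether a part of each rise remained is not settled. edgeR with plain totals called 5, while edgeR with TMM factors and DESeq2 each called 2, the falls of Purkinje cells and progenitors. With single mice left out, 2 to 7 types were called. The count was 2 without the vehicle KO mouse of pool 1 or of pool 3, or the NR KO mouse of pool 1 or of pool 2, and 3 without the NR KO mouse of pool 4. The falls of Purkinje cells and progenitors were kept in each of these fits.

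The scarcity of Purkinje and progenitor nuclei was also measured in 2 Control mice. The vehicle Control mouse of pool 4 had 1 Purkinje nucleus among 28371, a share of 0.00352% (95% Wilson interval 0.000622% to 0.0200%), and 0.941% progenitors (0.835% to 1.06%). The NR Control mouse of pool 2 had 1 Purkinje nucleus among 24855, a share of 0.00402% (0.000710% to 0.0228%), and 0.865% progenitors (0.757% to 0.988%). Progenitor shares in the 4 NR KO mice, in pool order, were 0.880%, 0.712%, 0.915% and 1.03%. They were 15.1%, 10.7% and 9.42% in the vehicle Control mice of pools 1, 2 and 3, and 13.6%, 8.57% and 13.6% in the NR Control mice of pools 1, 3 and 4. Vehicle KO mice ranged from 10.4% to 17.5%. These intervals cover counting error only.

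**Figure D1:**
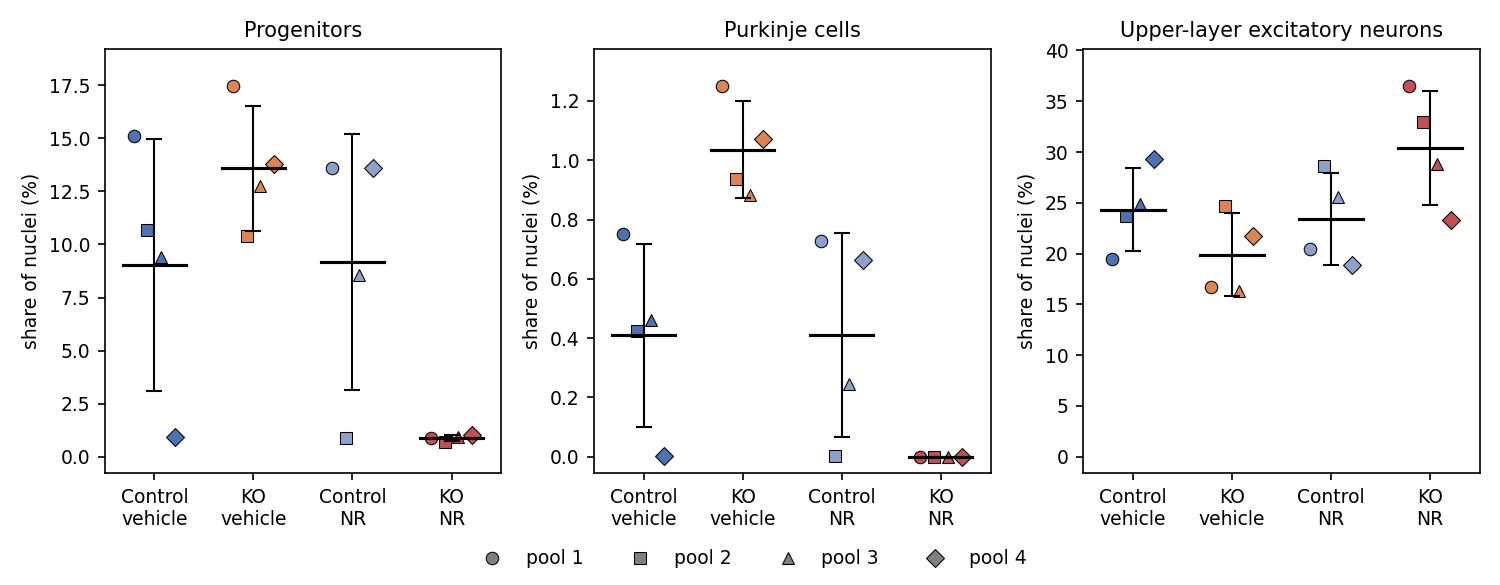
Shares of progenitors, Purkinje cells and upper-layer excitatory neurons (percent of nuclei) in each mouse of the 4 groups, with the marker giving the pool and the bars the group mean ± SD (n = 4). The 4 NR KO mice have 0 Purkinje nuclei and progenitor shares of 0.712% to 1.03%, and 1 mouse in each Control group lies at the same low level.

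Between NR and vehicle in Control mice, no share passed the test. Hippocampal neurons made up 1.09% ± 0.203 (SD, n = 4) with NR and 0.919% ± 0.212 with vehicle, a log2 odds difference of 0.26 (SE 0.20, higher in 4 of 4 pools). Ependymal cells, which line the ventricles, made up 1.56% ± 0.616 against 1.21% ± 0.343 (0.29, SE 0.40, higher in 3 of 4 pools). Microglia, the resident immune cells of the brain, made up 1.96% ± 0.254 against 2.38% ± 0.681 (-0.25, SE 0.34, lower in 3 of 4 pools). With 1 mouse left out these differences ranged more widely: 0.09 without the vehicle Control mouse of pool 1 to 0.41 without the NR Control mouse of pool 1 for hippocampal neurons, 0.11 without the NR Control mouse of pool 4 to 0.67 without that of pool 3 for ependymal cells, and -0.44 without the vehicle Control mouse of pool 4 to -0.08 without that of pool 1 for microglia. limma called 0 of 16 types (lowest adjusted p = 0.988), 0 at an unadjusted p under 0.05, and edgeR and DESeq2 called 0.

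Purkinje cells also fell in NR KO mice against both Control groups. Against vehicle Control mice, with 388 Purkinje nuclei of 100491, the share was at least 121-fold lower and the log2 odds difference was -6.30 (SE 1.55, limma adjusted p = 0.0195, lower in 4 of 4 pools). Against NR Control mice, with 421 of 101334, it was at least 130-fold lower, with a difference of -6.28 (SE 1.55, limma adjusted p = 0.0202, lower in 4 of 4 pools). Both folds use the floor over the group and cover counting error only. Both exact p values were 0.0286, and the within-person differences were -4.93 and -7.68 against vehicle Control and -4.93 and -7.62 against NR Control. The separation of the groups behind these exact p values and the count of 4 of 4 pools rested in 1 pool of each contrast on 1 Purkinje nucleus against 0, in the vehicle Control mouse of pool 4 and the NR Control mouse of pool 2. The Wilson intervals of these mice, up to 0.0200% and 0.0228%, overlap those of the NR KO mice of the same pools, 0% to 0.0161% and 0% to 0.0173%. Progenitors differed by -2.93 (SE 0.93, limma adjusted p = 0.0578) and -2.92 (SE 0.93, limma adjusted p = 0.0595), and did not pass. Each contrast had 1 of 16 types past the threshold in limma and 3 at an unadjusted p under 0.05, and each had 2 in edgeR and in DESeq2. The limma call against vehicle Control ended, with a count of 0, without the vehicle Control mouse of pool 1, 2 or 3 or without any of the NR KO mice. The call against NR Control ended, with a count of 0, without the NR Control mouse of pool 1, 3 or 4 or without any of the NR KO mice. Both counts were 2 without the vehicle Control mouse of pool 4 or without the NR Control mouse of pool 2. Both calls ended with the litter as a block, at -5.67 (limma adjusted p = 0.338) and -5.04 (limma adjusted p = 0.684).

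By the limma test, the difference in Purkinje share between NR and vehicle mice was not the same in the 2 genotypes. As 1 vehicle and 1 NR Control mouse also had only 1 Purkinje nucleus each, these values do not settle whether NR was the cause. Of 100 splits of the mice 7 called as many types, the real one included, and 8 of 100 within pools. The NR difference in KO minus that in Control mice was -8.90 log2 odds (SE 2.19, exact p = 0.0151, limma adjusted p = 0.0196), below 0 in 4 of 4 pools. Within persons it was -8.998 and -8.81. It was -6.64 (limma adjusted p = 0.577) with the litter as a block, and 0 types passed. The value for progenitors was -4.11 (SE 1.32, limma adjusted p = 0.0613) and did not pass. limma called 1 of 16 types, with 4 at an unadjusted p under 0.05. The count was 0 without the NR Control mouse of pool 1 or of pool 4, and 2 without the vehicle Control mouse of pool 1 or the NR Control mouse of pool 2. A centred log-ratio in place of the logit called 6 types, 4 above and 2 below 0.

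Of the broad classes, progenitors were the one with a change that passed in limma, and with the litter as a block 0 classes passed in any contrast. The class holds the progenitor type alone, and its fall with NR in KO mice had a log2 odds difference of -4.12 (SE 0.90, limma adjusted p = 0.00348, 4 of 4 pools). Against vehicle Control mice its difference was -2.93 (SE 0.90, limma adjusted p = 0.0493, lower in 3 of 4 pools), but this call was lost with the pool as a block, with a count of 0, and with the person as a block. It was kept with 1 mouse left out only where that mouse was the vehicle Control mouse of pool 4 or the NR Control mouse of pool 2, and in the other fits the count was 0. With vehicle, 0 of 9 classes passed between KO and Control in limma and in the exact permutation test, and 0 had an unadjusted limma p under 0.05. The same counts were 0, 0 and 0 for NR in Control mice, while 0 passed in limma with 1 unadjusted for NR KO against NR Control and 2 unadjusted for the interaction. For NR in KO mice the count was 2 without the vehicle KO mouse of pool 2 or the NR KO mouse of pool 4, and 3 without the NR Control mouse of pool 1 or 3 or the NR KO mouse of pool 3. It was 3 with the person as a block and 4 with shares of neurons or of non-neuronal nuclei. Leaving out the vehicle Control mouse of pool 1 or the NR Control mouse of pool 2 gave 1 class for NR KO against NR Control and for the interaction, and leaving out the vehicle Control mouse of pool 4 gave 1 for the former. The planned exact permutation test, adjusted over 9 classes, called 0 in each of the 6 contrasts, where at least 6 of the 9 would have to reach the smallest p of 0.0286 in a comparison of 2 groups, with exact p values under 0.05 for 2 classes with NR in KO mice, 1 in the interaction and 0 in the others.

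Excitatory neurons made up 27.6% ± 4.62 of nuclei (SD, n = 4) in vehicle Control, 23.6% ± 5.22 in vehicle KO, 27.0% ± 5.09 in NR Control and 35.0% ± 7.26 in NR KO mice. In the same order of groups, inhibitory neurons made up 14.9% ± 1.32, 13.6% ± 1.25, 15.3% ± 3.54 and 18.6% ± 2.30. Other neurons, from the hypothalamus, thalamus and hippocampus, made up 19.1% ± 3.33, 16.6% ± 3.59, 18.2% ± 2.90 and 15.8% ± 2.01. Progenitor and immature nuclei made up 9.05% ± 5.93, 13.6% ± 2.94, 9.16% ± 6.02 and 0.885% ± 0.133. Astroglia made up 14.8% ± 1.07, 16.4% ± 2.56, 15.8% ± 1.96 and 14.5% ± 2.42. The oligodendrocyte lineage made up 7.19% ± 0.479, 6.80% ± 1.68, 6.62% ± 1.29 and 6.37% ± 2.38. Vascular nuclei made up 3.53% ± 1.31, 4.31% ± 2.40, 3.96% ± 1.38 and 4.58% ± 2.81. Immune nuclei made up 2.38% ± 0.681, 2.92% ± 1.00, 1.96% ± 0.254 and 2.10% ± 0.946. Ependymal and choroid plexus nuclei made up 1.21% ± 0.343, 1.64% ± 0.494, 1.56% ± 0.616 and 1.40% ± 0.544. This last class held ependymal cells alone, as no choroid plexus type was annotated. Astroglia were astrocytes alone, the oligodendrocyte lineage was oligodendrocyte progenitors alone, and immune nuclei were microglia alone.

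The serine biosynthesis score, which summarises genes that make serine from a glycolytic intermediate, rose in 11 of 15 cell types of vehicle KO mice. In endothelial cells it rose from 0.0192 ± 0.0145 to 0.130 ± 0.0128 (SD, n = 4), a difference of 0.111 (SE 0.0125, limma adjusted p = 3.89e-05) with within-person differences of 0.102 and 0.120. It rose by 0.0743 in microglia (SE 0.0143, limma adjusted p = 0.00196), by 0.0408 in astrocytes (SE 0.00488, limma adjusted p = 4.25e-05) and by 0.0465 in upper-layer excitatory neurons (SE 0.0107, limma adjusted p = 0.00742). In interneurons from the medial ganglionic eminence it rose by 0.0544 (SE 0.00838, limma adjusted p = 0.000403). The other rises, in the type named unknown, mural cells, progenitors, oligodendrocyte progenitors, deeper-layer excitatory neurons and interneurons from the lateral or caudal ganglionic eminence, lay between 0.0343 and 0.0721. All 15 estimates were above 0, with a median of 0.0437, and each of the 11 rises was seen in 4 of 4 pools.

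The ATF4 regulon score, for targets of a transcription factor of the integrated stress response, rose in 5 of 15 types of vehicle KO mice. It rose by 0.0166 in upper-layer excitatory neurons (SE 0.00345, limma adjusted p = 0.00369), by 0.0133 in deeper-layer excitatory neurons, by 0.0125 in ependymal cells, by 0.0115 in astrocytes and by 0.00854 in interneurons from the medial ganglionic eminence. The hypoxia score rose by 0.0321 in endothelial cells (SE 0.00574, limma adjusted p = 0.00106). The Biocarta death pathway score rose by 0.0108 in oligodendrocyte progenitors and by 0.0148 in ependymal cells, the androgen response score by 0.0332 in microglia and the G2/M checkpoint score by 0.0103 in upper-layer neurons. All of these were higher in 4 of 4 pools. The apoptosis score was above 0 in difference in 15 of 15 types and passed in 0 (lowest limma adjusted p = 0.0793, 2 unadjusted under 0.05). Scores for the mitotic spindle, macroautophagy and regulated necrosis passed in 0 types in limma, with 3, 1 and 1 unadjusted.

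Over 150 pairs of score and cell type limma called 21, all higher in vehicle KO mice, with 41 at an unadjusted p under 0.05. How the authors chose the 10 gene sets was not given in the sources used here, so a score that moves in the direction of its name is not independent evidence. Among nuclei within a UMI window, 13 pairs passed, 12 higher and 1 lower, and 10 of the 21 were kept. These were 7 of the 11 serine calls, 2 of the 5 ATF4 calls (upper-layer and deeper-layer neurons) and endothelial hypoxia. With means in place of medians 34 passed, 27 higher and 7 lower. With the litter as a block 23 passed, 18 higher and 5 lower, and 14 of the 21 were kept. These were 9 of the 11 serine calls, 2 of the 5 ATF4 calls (upper-layer neurons 0.0187 and deeper-layer neurons 0.0149), endothelial hypoxia, microglial androgen response and upper-layer G2/M. The person as a block kept 3 of the 5 ATF4 calls and all calls of the other scores. The planned score over all nuclei of a mouse did not pass: serine differed by 0.0472 and ATF4 by 0.0136, each with an exact p of 0.0286 and an adjusted exact p of 0.377 over 66 tests, of which at least 38 would have to reach 0.0286 for such a comparison to pass.

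**Figure D2:**
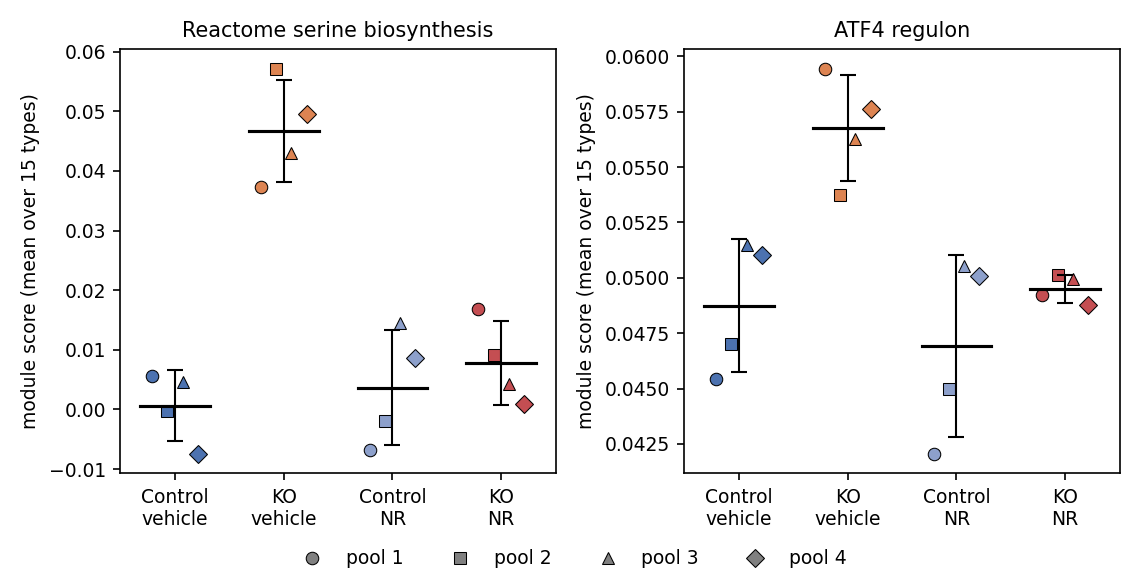
Serine biosynthesis and ATF4 regulon scores of each mouse (mean of the medians of 15 cell types, score units) in the 4 groups, with the marker giving the pool and the bars the group mean ± SD (n = 4). Serine means are 0.0468 in vehicle KO mice and 0.000634, 0.00360 and 0.00780 in vehicle Control, NR Control and NR KO mice.

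The serine biosynthesis score fell in 10 of 15 cell types of KO mice given NR. It fell by 0.0893 in endothelial cells (SE 0.0125, limma adjusted p = 0.000394), by 0.0758 in progenitors (SE 0.0116, limma adjusted p = 0.000537), by 0.0654 in microglia and by 0.0567 in mural cells. It fell by 0.0540 in the unknown type, by 0.0357 in upper-layer neurons, by 0.0329 in oligodendrocyte progenitors, by 0.0328 and 0.0191 in the interneurons from the medial and the lateral or caudal eminence, and by 0.0291 in astrocytes. All 15 estimates were below 0, with a median of -0.0328, and each of the 10 falls was seen in 4 of 4 pools. In progenitors the 2 Control mice with few of them also had low serine scores, -0.0276 (vehicle, pool 4) and -0.03996 (NR, pool 2), while the other Control mice ranged from 0.00889 to 0.0179 and NR KO mice from -0.0409 to -0.0127. The ATF4 regulon score fell by 0.0155 in ependymal cells, by 0.0143 in upper-layer neurons, by 0.0124 in deeper-layer neurons and by 0.0117 in astrocytes, each in 4 of 4 pools. The hypoxia score fell by 0.0398 in endothelial cells (4 of 4 pools) and by 0.0216 in the unknown type (3 of 4 pools), and the apoptosis score fell by 0.0253 in endothelial cells (4 of 4 pools).

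In progenitors, the G2/M checkpoint score rose with NR in KO mice from 0.0501 ± 0.0154 to 0.187 ± 0.0164 (SD, n = 4), a difference of 0.137 (SE 0.0231, limma adjusted p = 0.000740). The mitotic spindle score of progenitors rose by 0.0673 (SE 0.0135, limma adjusted p = 0.00340), and both were higher in 4 of 4 pools. The remaining progenitors of the 2 Control mice with few of them had G2/M scores of 0.148 and 0.165, while the other Control mice ranged from 0.0543 to 0.0703. Within the UMI window the progenitor differences were 0.0615 for G2/M and 0.0154 for the spindle, and neither passed. The NR KO mice held 158 to 247 progenitors each, with medians of 14699 to 17649 UMIs against 6273 over all progenitors. How many of them lay in the window was not counted here, so progenitor values in the window can rest on few nuclei. Over 150 pairs limma called 19, with 2 higher and 17 lower in NR KO mice, and 34 at an unadjusted p under 0.05. Within the UMI window 8 were kept, with no others called. These were 5 serine calls (astrocytes, endothelial cells, microglia, oligodendrocyte progenitors and progenitors), 2 ATF4 calls (upper-layer and deeper-layer neurons) and endothelial hypoxia. Of the 19 calls 3 were kept with the litter as a block, with no others called: serine in astrocytes (-0.0324) and endothelial cells (-0.0930) and endothelial hypoxia (-0.0423). Progenitor G2/M was then 0.124 (limma adjusted p = 0.0847). The scores for the death pathway, androgen response, macroautophagy and regulated necrosis passed in 0 types in limma, with 1, 2, 1 and 3 unadjusted.

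Averaged over 15 cell types with equal weight, the serine score was 0.000634 ± 0.00595 in vehicle Control, 0.0468 ± 0.00855 in vehicle KO, 0.00360 ± 0.00965 in NR Control and 0.00780 ± 0.00698 in NR KO mice (SD, n = 4). The vehicle KO mice lay above every mouse of the other groups. KO against Control with vehicle gave 0.0461 and NR against vehicle in KO gave -0.0390, each with an exact p of 0.0286 (adjusted 0.286 over 60 tests, of which at least 35 would have to reach 0.0286 to pass). Within persons these were 0.0411 and 0.0512, and -0.0376 and -0.0403. The ATF4 score was 0.0487 ± 0.00299, 0.0568 ± 0.00240, 0.0469 ± 0.00411 and 0.0495 ± 0.000631 in the same order of groups. Its differences were 0.00802 and -0.00726, each with an exact p of 0.0286 (adjusted 0.286), and within persons 0.00961 and 0.00643, and -0.00851 and -0.00601. Within the UMI window the ATF4 differences were 0.00616 (exact p = 0.143) and -0.00722 (exact p = 0.0286). Within litters the serine differences were 0.0450 (SE 0.00718) and -0.0405 (SE 0.00894), and the ATF4 differences 0.00752 (SE 0.00278) and -0.00669 (SE 0.00346). The planned score over all nuclei of a mouse did not pass for NR in KO mice either, with -0.0367 for serine and -0.0135 for ATF4, each with an exact p of 0.0286 and an adjusted exact p of 0.377 over 66 tests.

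No score passed in limma in the other comparisons of 2 groups. NR against vehicle in Control mice had 0 of 150 pairs past the threshold and 4 unadjusted, with regulated necrosis in ependymal cells (0.00950) and in interneurons from the medial eminence (0.00585) and serine in ependymal cells (-0.0271) at the smallest p. NR KO against vehicle Control had 0 and 8 unadjusted, the smallest adjusted p being 0.0615 for progenitor G2/M (0.105, SE 0.0231, higher in 4 of 4 pools). NR KO against NR Control had 0 and 3 unadjusted, the smallest adjusted p being 0.0882 for the same pair (0.101, SE 0.0231, higher in 4 of 4 pools). Without the vehicle Control mouse of pool 4 the counts were 3 and 1, and without the NR Control mouse of pool 2 they were 1 and 3.

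The NR effect on the serine score differed between genotypes in 7 of 15 cell types. The difference of the 2 effects was -0.0943 in endothelial cells (SE 0.0176, limma adjusted p = 0.0130), -0.0763 in microglia, -0.0746 in progenitors, -0.0708 in the unknown type, -0.0364 in oligodendrocyte progenitors, -0.0326 in astrocytes and -0.0295 in interneurons from the lateral or caudal eminence. It was below 0 in 4 of 4 pools for these types except the oligodendrocyte progenitors, with 3 of 4. Endothelial hypoxia differed by -0.0342 (3 of 4 pools), and progenitor G2/M and spindle scores by 0.133 and 0.0676 (4 of 4 pools each). On the equal-weight serine score the difference of effects was -0.0419 (exact p = 0.00857, adjusted 0.286), and within persons -0.0419 and -0.0420. On the equal-weight ATF4 score it was -0.00543 (exact p = 0.162, adjusted 0.571), within persons -0.00780 and -0.00307, within the UMI window -0.00406 (exact p = 0.421) and within litters -0.00473 (SE 0.00445). The planned scores over all nuclei of a mouse did not pass for the difference of effects, with -0.0420 for serine (exact p = 0.00612, adjusted 0.377) and -0.0129 for ATF4 (exact p = 0.0355, adjusted 0.391). limma called 10 of 150 pairs, 2 above and 8 below 0, with 23 unadjusted. The count was 0 with the litter as a block, with -0.0970 for endothelial serine (limma adjusted p = 0.0753), and 2 within the UMI window, for serine in endothelial cells and progenitors. The progenitor values include the low scores of the 2 Control mice given above, and in the window they can rest on few nuclei. The count of calls was 6 without the vehicle Control mouse of pool 2 or the vehicle KO mouse of pool 3. It was 5 without the NR KO mouse of pool 4. It was 4 without the vehicle KO mouse of pool 4 or the NR Control mouse of pool 3. It was 2 without the NR Control mouse of pool 4 and 1 without the vehicle KO mouse of pool 2.

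Some score calls rested on single mice. The 11 serine calls between vehicle KO and vehicle Control mice were kept with any 1 mouse left out, as were 3 of the 5 ATF4 calls and endothelial hypoxia. The androgen response call in microglia was lost without the vehicle Control mouse of pool 4 (0.0263) or the vehicle KO mouse of pool 3 (0.0312). The upper-layer G2/M call was lost without the vehicle Control mouse of pool 2 or 4 or the vehicle KO mouse of pool 1 or 3 (0.00887 to 0.0104). The ependymal death pathway call was lost without the vehicle Control mouse of pool 1, 2 or 3 or the vehicle KO mouse of pool 3 or 4 (0.0123 to 0.0154). The ATF4 calls in ependymal cells (0.00899 to 0.0125) and in interneurons from the medial eminence (0.00655 to 0.00905) were lost in 11 and 13 of the 16 fits that left out 1 mouse. For NR in KO mice, 7 of the 10 serine calls and 4 of the 4 ATF4 calls were kept in every such fit. The serine call in interneurons from the medial eminence was lost without the vehicle KO mouse of pool 2 or the NR KO mouse of pool 3 or 4 (-0.0286 to -0.0268). That in interneurons from the lateral or caudal eminence was lost without the vehicle KO mouse of pool 2, 3 or 4 or the NR KO mouse of pool 3 or 4 (-0.0193 to -0.0154). That in upper-layer neurons was lost in 6 fits (-0.0382 to -0.0261), endothelial apoptosis in 4 (-0.0238 to -0.0207) and hypoxia of the unknown type in 10 (-0.0227 to -0.0169).

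With the pool as a block, some score calls ended although their differences stayed the same. Between vehicle KO and vehicle Control mice this was ATF4 in interneurons from the medial eminence (0.00854, limma adjusted p = 0.0944). For NR in KO mice it was endothelial apoptosis (-0.0253, limma adjusted p = 0.0650), hypoxia of the unknown type (-0.0216, limma adjusted p = 0.0681) and serine in interneurons from the lateral or caudal eminence (-0.0191, limma adjusted p = 0.0549). For the interaction it was the progenitor spindle score (0.0676, limma adjusted p = 0.0748), serine in microglia (-0.0763, limma adjusted p = 0.0525) and serine in interneurons from the lateral or caudal eminence (-0.0295, limma adjusted p = 0.0589).

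Progenitors of NR KO mice carried more UMIs per nucleus than those of vehicle KO mice. The geometric mean of the mouse medians rose from 6315 to 16170 UMIs, a log2 difference of 1.36 (SE 0.35, limma adjusted p = 0.0282, exact p = 0.0286). The vehicle Control mouse of pool 4 and the NR Control mouse of pool 2, which had few progenitors, had medians of 16336 and 16138 UMIs. The call was lost, with a count of 0, when the pool or the litter was a block, and without the vehicle KO mouse of pool 2, 3 or 4 or any of the NR KO mice. Of the other types 0 passed in limma. Endothelial cells of vehicle KO mice had a log2 difference of -0.62 from those of vehicle Control mice (SE 0.23, limma adjusted p = 0.188), and that contrast had 0 of 15 types past the threshold, with 3 unadjusted and 1 past it without the vehicle KO mouse of pool 4. The remaining contrasts also had 0 in limma, with 1 unadjusted for NR in Control mice, 3 for NR KO against vehicle Control, 1 for NR KO against NR Control and 1 for the interaction. Without the NR Control mouse of pool 2, the last 3 of these each had 1 type past the threshold, and without the vehicle Control mouse of pool 4 the comparisons of NR KO mice with each Control group had 1.

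Mice had 25123 ± 4065 nuclei (SD, n = 4) in vehicle Control, 24346 ± 1427 in vehicle KO, 25334 ± 1533 in NR Control and 23498 ± 874 in NR KO. The median UMI count per nucleus was 10610 ± 1223, 9429 ± 848, 9924 ± 294 and 10034 ± 640 in the same order. The share of called cells kept in the cell table was 88.8% ± 0.561 in vehicle KO and 89.8% ± 0.369 in vehicle Control mice (exact p = 0.0571). Over 54 exact permutation tests of such measures the lowest adjusted p was 0.514, and at least 31 of them would have to reach 0.0286 for a comparison of 4 mice with 4 to pass, so the absence of a call was largely set by the design. The deposited weight, whose object is not stated, was 57.3 mg ± 6.95 in vehicle KO (n = 4) and 79.8 mg ± 19.6 in vehicle Control mice (n = 4, exact p = 0.0571, adjusted 0.143). It was 68.0 mg ± 4.58 in NR KO (n = 3, exact p = 0.0571 against vehicle KO, adjusted 0.143) and 74.0 mg ± 8.04 in NR Control mice (n = 4).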

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

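The tests of explanations in this part were chosen after the results they concern had been seen, apart from the comparison with other splits of the mice, which was planned except for the interaction splits within pools.

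Of 130 groups of 4 mice, 6 held a mouse far from the other 3 by Dixon's criterion, which chance meets in about 1 in 20 groups (6.5 expected here). Hypothalamic and thalamic neurons made up 13.5% in the vehicle Control mouse of pool 1 (others 19.2% to 20.2%). Oligodendrocyte progenitors made up 4.70% in the NR Control mouse of pool 3 (others 7.06% to 7.37%). Interneurons from the lateral or caudal eminence made up 2.34% in the NR KO mouse of pool 3 (others 2.65% to 2.71%). The NR KO mouse of pool 2 had 22193 nuclei (others 23861 to 24055). The vehicle KO mouse of pool 2 had 5019 genes per nucleus at matched depth (others 4483 to 4566). The equal-weight G2/M checkpoint score was 0.00917 in the NR Control mouse of pool 4 (others 0.000926 to 0.00228).

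The NR effect differed between KO and Control mice by the limma interaction test in 11 results. For shares this was Purkinje cells (-8.90 log2 odds, limma adjusted p = 0.0196). For the serine biosynthesis score it was endothelial cells (-0.0943, limma adjusted p = 0.0130), microglia (-0.0763, limma adjusted p = 0.0320), progenitors (-0.0746, limma adjusted p = 0.0207), the unknown type (-0.0708, limma adjusted p = 0.0240), oligodendrocyte progenitors (-0.0364, limma adjusted p = 0.0290), astrocytes (-0.0326, limma adjusted p = 0.0207) and interneurons from the lateral or caudal eminence (-0.0295, limma adjusted p = 0.0290). The others were endothelial hypoxia (-0.0342, limma adjusted p = 0.0240), progenitor G2/M checkpoint (0.133, limma adjusted p = 0.0261) and progenitor mitotic spindle (0.0676, limma adjusted p = 0.0469).

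Almost no Purkinje nuclei and few progenitors were found in 6 mice, the 4 NR KO mice and 2 Control mice. The combination of knockout and NR cannot account for all 6, since 2 were Control mice with 1 Purkinje nucleus each, which says nothing about the cause in the NR KO mice. The isolating person or the pool can be excluded as the sole cause, since each person's and each pool's mice included at least 2 with more than 1 Purkinje nucleus. A batch of isolation or dissection that took in only some of a person's mice was not tested. The litter was not tested as a cause. Both Control mice came from the litter of the NR KO mice of pools 2 and 4, in which other mice had many Purkinje nuclei. No mouse of the only other litter with several mice lacked them. Cerebellar tissue missing from these hemi-brains could account for both losses, as Purkinje cells and many progenitors at this age lie in the cerebellum, and the highest progenitor share among the 6 mice was 1.03%. That share is part of the pattern itself, and notes on the dissection of single mice were not used here. The progenitors that remained in the 6 mice had median UMIs of 14699 to 17649 and G2/M scores of 0.148 to 0.205. In the other 10 mice these were 5368.5 to 7468 and 0.0360 to 0.0703. The 2 Control mice thus lay nearer to the NR KO mice than to the other Control mice in both, which names no cause. Missing tissue remains an open hypothesis, and an effect of NR on cerebellar cells in KO mice is not excluded for the 4 NR KO mice.

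The serine biosynthesis and ATF4 scores were higher in vehicle KO mice than in vehicle Control and NR KO mice. A difference in UMIs per nucleus can be excluded as the sole cause for the equal-weight serine score in both contrasts (0.0434 and -0.0386 within the UMI window, 0.0461 and -0.0390 without it). The fall of ATF4 with NR kept its size in the window (-0.00722, SE 0.00300, exact p = 0.0286, against -0.00726, SE 0.00200), with no overlap between the mice. With the litter as a block it was -0.00544 (SE 0.00509) in the window. These values argue against depth as the sole cause of that fall without excluding it. Depth is not excluded for the rise of ATF4 in vehicle KO mice (0.00616, SE 0.00300, exact p = 0.143 in the window, 0.00802, SE 0.00200 without it), where the mice of the 2 groups overlapped. The person who isolated the nuclei can be excluded, since each handled 2 mice of every group and within persons vehicle KO mice lay above vehicle Control mice by at least 0.0411 for serine and 0.00643 for ATF4. Missing cerebellar tissue as the sole cause of the falls with NR was weighed on the average over 6 forebrain neuron types. These were upper-layer and deeper-layer excitatory neurons, medium spiny neurons, interneurons from the medial and the lateral or caudal eminence, and hippocampal neurons. Hypothalamic and thalamic neurons were left out, and whether the 6 types held any cerebellar cells was not checked. Over nuclei of any depth the values argue against it. The serine difference was -0.0229 (SE 0.00703), and -0.0266 (SE 0.0100) with the litter as a block. The ATF4 difference was -0.00745 (SE 0.00191), and -0.00810 (SE 0.00328) with that block. However, the serine scores of the NR KO mice of pools 1 and 2 (0.000435 and -0.00456) lay close below the lowest vehicle KO mouse (0.00188). In the UMI window ATF4 was -0.00645 (SE 0.00219, exact p = 0.0286), and -0.00710 (SE 0.00373) with the litter. Serine was -0.0210 there (SE 0.00943, exact p = 0.143), at the weakest -0.0136 with 1 mouse left out, and -0.0171 (SE 0.0123) with the litter. At matched depth missing tissue is thus not excluded as the sole cause of the serine fall. As a part of the cause it stays open in the 5 glial and vascular types that passed for serine, where cerebellar and forebrain cells cannot be told apart.

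The share of endothelial nuclei differed by the person who isolated the nuclei: 2.18% ± 0.824 in the 8 mice of person 1 and 0.642% ± 0.135 in the 8 mice of person 2, with the same direction in 4 of 4 groups. The exact permutation p within groups was 0.00154, the smallest that 1296 arrangements can give, and the adjusted exact p over 16 types was 0.00617. The pools can be excluded as the cause, since within pools and groups the persons still differed by 1.72 log2 odds (SE 0.315). The p restates the difference and names no cause, so whether the isolation of nuclei or something else that differed between the mice of the 2 persons lay behind it can't be told. No biological explanation was tested, and each person handled 2 mice of every group.

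Other splits of the same mice into 4 and 4 were compared with the real one, by how many of 35 splits (100 drawn ones for the interaction) called as many results, the real one included. For cell type shares the number was 35 between KO and Control with vehicle (real 0, highest other 0), 2 for NR in KO mice (real 6, highest other 7), 35 for NR in Control mice (real 0, highest other 2), 3 for NR KO against vehicle Control (real 1, highest other 3), 3 for NR KO against NR Control (real 1, highest other 3) and 7 for the interaction (real 1, highest other 7). By these numbers chance can't be excluded for any of the counts of shares above 0. A real count of 0 is equalled by every split, so the comparison tests nothing for those contrasts. For NR in KO mice the split by person called 7 types, as many as the highest, and with the person as a block the real groups called 7, with all 6 calls kept. For NR KO against NR Control the split by person called 2, and the blocked value was 1, with the call kept. Among the 8 splits that part the mice of all 4 pools, the real one was the only one with as many calls for NR in KO mice (highest other 0) and for NR KO against NR Control (highest other 0), but 8 are too few for a share under 0.05.

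For broad classes in limma the numbers of splits were 35 between KO and Control with vehicle (real 0, highest other 1), 4 for NR in KO mice (real 1, highest other 6), 35 for NR in Control mice (real 0, highest other 1), 3 for NR KO against vehicle Control (real 1, highest other 2), 35 for NR KO against NR Control (real 0, highest other 4) and 100 for the interaction (real 0, highest other 2). Chance can't be excluded for NR in KO mice or for NR KO against vehicle Control. The real counts of 0 are equalled by every split, so nothing is tested for them. The split by person gave the 6 for NR in KO mice, where the blocked value was 3, and the 4 for NR KO against NR Control, where the blocked value was 0. Splits that call many more classes than the real groups point to a structure of the samples, and the person is such a structure here.

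For UMIs per nucleus by cell type the numbers of splits were 35 between KO and Control with vehicle (real 0, highest other 8), 1 for NR in KO mice (real 1, highest other 0), 35 for NR in Control mice (real 0, highest other 0), 35 for NR KO against vehicle Control (real 0, highest other 4), 35 for NR KO against NR Control (real 0, highest other 1) and 100 for the interaction (real 0, highest other 3). For the contrasts with a real count of 0 the comparison could not come out otherwise and tests nothing. As the pools pair the mice, the 1 call for NR in KO mice is to be compared with the 8 splits that part all 4 pools, of which the real one alone gave a call (highest other 0). These are too few for a share under 0.05, and the call was lost with the pool or the litter as a block and without any of 7 single mice. The split with 8 calls among vehicle mice was not the split by person, which called 0, and points to another structure of the samples, whose source was not tested.

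For scores by cell type the numbers of splits were 1 between KO and Control with vehicle (real 21, highest other 1), 1 for NR in KO mice (real 19, highest other 0), 35 for NR in Control mice (real 0, highest other 1), 35 for NR KO against vehicle Control (real 0, highest other 0), 35 for NR KO against NR Control (real 0, highest other 18) and 2 for the interaction (real 10, highest other 10). Where the real count was 0, every split was bound to give as many, so the comparison tests nothing there. Among the 8 splits that part all 4 pools, the real one was the only one with as many calls for KO against Control with vehicle and for NR in KO mice (highest other 0 in both), but 8 are too few for a share under 0.05, while the other 27 of the 35 splits set mice of the same pool together. The drawn splits for the interaction were not limited by pool, so 100 that exchange treatments only between mice of the same genotype and pool were drawn as well, of which 3 gave as many calls, the real one included (highest other 16). That is a share under 0.05, but another grouping of the same mice called more pairs than the real one. For the interaction in shares 8 of 100 such splits gave as many (highest other 6). The 3 contrasts had 23, 3 and 0 calls with the litter as a block, so for NR in KO mice and the interaction the litter is not excluded as a part of the cause. The split with 18 calls among the NR mice parts all 4 pools and points to a structure of the samples other than the group, whose source was not tested.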

How the results depend on the processing

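Alternatives added after the data were seen were the person and the litter as blocks, the removal of Purkinje and progenitor nuclei, the removal of the 2 Control mice with at most 1 Purkinje nucleus, and all alternatives for scores by cell type. No share passed between KO and Control with vehicle or for NR in Control mice under any alternative. For NR in KO mice the 6 changed shares became 2 with edgeR and TMM factors, 2 with DESeq2 and 0 without Purkinje and progenitor nuclei, 9 (7 higher, 2 lower) with the centred log-ratio, and 2 to 7 with 1 mouse left out. For NR KO against vehicle Control the 1 became 2 with edgeR and plain totals, 2 with edgeR and TMM factors, 2 with DESeq2, 2 with log2 nuclei as a covariate and 2 without the 2 Control mice. It became 0 with the arcsine square root, the pseudocount of 5, only the 2 groups compared, nuclei over the 95th percentile of UMIs left out, or Purkinje and progenitor nuclei left out, and 0 to 2 with 1 mouse left out. For NR KO against NR Control the 1 became 2 with both edgeR fits, DESeq2, log2 nuclei as a covariate and without the 2 Control mice, and 0 with the arcsine square root, the pseudocount of 5, nuclei over the 95th percentile left out, or Purkinje and progenitor nuclei left out, and 0 to 2 with 1 mouse left out. For the interaction the 1 became 2 with both edgeR fits, DESeq2, log2 nuclei as a covariate and without the 2 Control mice, 6 with the centred log-ratio, 0 with nuclei over the 95th percentile left out or Purkinje and progenitor nuclei left out, and 0 to 2 with 1 mouse left out. For broad classes with NR in KO mice the 1 became 4 with shares of neurons or of non-neuronal nuclei, 3 with the person as a block, 2 without the 2 Control mice and 1 to 3 with 1 mouse left out. For NR KO against vehicle Control the 1 class became 0 with the pool as a block, 2 with shares of neurons or of non-neuronal nuclei, 0 with the person as a block and 0 to 1 with 1 mouse left out. For NR KO against NR Control and for the interaction the 0 classes became 1 without the 2 Control mice and 0 to 1 with 1 mouse left out. For UMIs per nucleus the 1 type with NR in KO mice became 0 with the pool as a block and 0 to 1 with 1 mouse left out. The 0 types became 1 without the 2 Control mice for NR KO against vehicle Control, NR KO against NR Control and the interaction, with 0 to 1 for these and for KO against Control with vehicle with 1 mouse left out. Of score and cell type pairs, the 21 between KO and Control with vehicle became 34 (27 higher, 7 lower) with means and 13 in the UMI window, and 16 to 26 with 1 mouse left out. The 19 for NR in KO mice became 8 in the UMI window and 14 to 22 with 1 mouse left out. The 0 for NR KO against vehicle Control became 1 with the person as a block, 4 without the 2 Control mice and 0 to 3 with 1 mouse left out. The 0 for NR KO against NR Control became 1 with the person as a block, 3 without the 2 Control mice and 0 to 3 with 1 mouse left out. The 10 of the interaction became 2 in the UMI window and 1 to 11 with 1 mouse left out. In the UMI window the progenitor mitotic spindle difference reversed for NR KO against NR Control (-0.00308), and the interaction reversed for the progenitor mitotic spindle score (-0.00276) and for serine in interneurons from the lateral or caudal eminence (0.00215). The window holds fewer nuclei, and the cause was not tested; nor was it tested for the other changes. The pool as a block moved no other count by over 1.5 times, but ended 7 named score calls, 1 between KO and Control with vehicle, 3 for NR in KO mice and 3 of the interaction. The litter as a block ended every call of shares (6, 1, 1 and 1 became 0), classes (1 and 1 became 0) and UMIs (1 became 0) and took scores to 23 for KO against Control with vehicle, 3 for NR in KO mice and 0 for the interaction, while each named call kept its direction. This fit compares 13 mice within 2 litters. Equal-weight serine kept its direction under every alternative and its exact p of 0.0286 with means and in the UMI window in both of its 2-group contrasts, with 0.0427 to 0.0493 for KO against Control with vehicle and -0.0421 to -0.0355 for NR in KO mice with 1 mouse left out. Equal-weight ATF4 went from 0.00802 (exact p = 0.0286) to 0.00616 (exact p = 0.143) in the UMI window for KO against Control with vehicle. Settings without a minimum of nuclei and with a minimum of 50 were void, as they changed no type tested. A sex covariate was not run, as sex is not in the tables used, and neither was another annotation level, as the clusters equal the types.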

Other observations

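The comparison of Purkinje nuclei with progenitor nuclei was chosen after the shares of both types had been seen.

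Per 100 progenitor nuclei, vehicle KO mice had 7.72 ± 0.940 Purkinje nuclei (SD, n = 4, range 6.93 to 9.03) and vehicle Control mice 3.54 ± 2.16, with 0.375 in the mouse of pool 4 and 3.95 to 4.97 in the others. NR Control mice had 3.39 ± 2.22, with 0.465 in the mouse of pool 2 and 2.88 to 5.35 in the others, and NR KO mice had 0. The exact permutation p between vehicle KO and vehicle Control mice was 0.0286 (adjusted exact p = 0.0571 over the 2 contrasts without NR KO mice, whose ratios were 0 throughout). As 0.0286 is the smallest p that 4 against 4 mice can give, 1 of 2 contrasts alone cannot pass, so the adjusted value says nothing about the difference. Over all 6 contrasts, 4 of them with the NR KO mice, it was 0.0343. Every vehicle KO mouse lay above every vehicle Control mouse, but whether the samples held the same parts of the cerebellum was not tested.

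Several other shares differed between the persons who isolated the nuclei, given here for person 1 and then person 2, 8 mice each. Mural cells made up 3.42% and 1.95%, the unknown type 0.841% and 0.260%, and oligodendrocyte progenitors 7.89% and 5.60% (exact p = 0.00154 each). Ependymal cells made up 1.78% and 1.13% (exact p = 0.00617), hypothalamic and thalamic neurons 14.5% and 18.3% (exact p = 0.00926) and astrocytes 16.5% and 14.2% (exact p = 0.0154).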
